A study of Homo sapiens with 4 samples.

How the data were processed

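The series holds 4 TT-seq libraries of HEK293 degron cells, 2 from cells transfected with RPB1 carrying a 26x wild-type CTD and 2 from cells transfected with RPB1 carrying a 26x Y1T/T4Y CTD; groups and replicate numbers were taken from the sample titles and treatment labels. Per the labels' protocols, cells were labelled with 1 mM 4-thiouridine for 20 min, 150 µg of total RNA per experiment received labelled yeast RNA at 1 part in 100, RNA was fragmented with alkali, biotinylated, enriched on streptavidin beads and made into strand-marking libraries.

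The values used are counts per gene as deposited by the authors, in a human and a yeast table with 1 column per library and no normalization. The submitters' processing notes name Trim Galore 0.6.10, STAR, Picard 3.1.1, SAMtools 1.14 and featureCounts 2.0.1 and the human build hg38, without role or order; the STAR version, the annotation release, the yeast build, the strand setting and any duplicate removal are not given in the sources used here. Per the file headers each gene has a chromosome, start, end and strand, and the length equals end minus start plus 1 for 100% of human genes, so that introns are counted with exons. All 4235 genes nested in a same-strand gene with over 2000 counts were listed at 0, while 4232 of 5958 genes nested in an opposite-strand gene of that depth had counts. Reads shared by same-strand genes were therefore left uncounted and strand was used, which removes intronic snoRNAs and other nested genes from every result. How reads with several places in the genome were counted is not given in the sources used here, so multicopy RNAs are uncertain.

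The human table gives versioned Ensembl identifiers. Gene symbols were assigned by matching each interval to a RefSeq table of GRCh38.p14, the same build: overlap over union of at least 0.8, or of at least 0.5 with 1 end within 10 bp, the best match in both directions, and the next best under 0.5. This named 34730 of 60708 identifiers (57.2%, holding 87.8% of human counts); 25338 of these share at least 1 end with the RefSeq gene, and 1895 ambiguous identifiers stayed unnamed. RefSeq names mitochondrially encoded genes without a prefix (RNR1, COX1). Pseudogenes caught by the patterns of the gene lists were left out of the lists.

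The human to yeast ratio is the summed human counts over the summed yeast counts, compared by a two-sided exact permutation test, whose smallest p with 2 against 2 libraries is 0.333. Genes were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) after filterByExpr, in 2 fits: relative to the human library, with TMM on human counts, and scaled to the spike-in, with the library size set to the yeast total times the TMM factor of the yeast counts. Adjusted p are Benjamini-Hochberg values and the threshold was an FDR of 0.05; SE is the log2 fold change over the root of F. CPM are the TMM-scaled values of edgeR's cpm function on human counts, computed here from the deposited counts. Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) for lists with at least 3 tested members, 25 of 26; no member of the RNA polymerase I list was tested. The other lists covered histone, RNA polymerase II snRNA, RNA polymerase III, mitochondrially encoded, cytosolic ribosomal protein, snoRNA host, ribosome biogenesis, immediate early, heat shock, stress response, p53, cholesterol, polymerase subunit, Mediator, Integrator, elongation, 3' end, splicing, replication, G2/M, interferon, respiratory chain and ZNF genes and markers of other cell types. Adjustment over the list alone applies Benjamini-Hochberg to the members' p. Downstream neighbours were compared with 10000 random lists matched in 20 bins of mean expression, and library pairs used log2 CPM with a prior count of 2.

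Named genes follow a rule written before the data were examined: POLR2A; the 8 largest rises and 8 largest falls relative to the human library, and the 4 of each scaled to the spike-in, with FDR under 0.05, a proper symbol, a mean of at least 50 counts in the higher group and no overlap between groups; and the 2 members of each list with the lowest p. Other members and genes named beside these were chosen after their values were seen.

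Depth ranged from 21322531 to 28183172 human counts and 8368890 to 13339834 yeast counts per library. Replicates differed beyond sampling noise (chi-square per degree of freedom 6.64 and 3.07 over genes with at least 20 counts), so none was a copy of another. The fits were tested on simulated counts with 200 changed genes. Relative to the human library, 44% of 100 genes changed 1.5-fold and 63% of 100 changed 2-fold were called among 23904 genes, with 0 unchanged genes called. Scaled to the spike-in without library noise, 51% and 64% of 100 genes each were called among 23935 genes, with 5 unchanged genes. With no gene changed and a library noise of 0.301 on the log2 scale, as between the observed ratios, 10 of 100 draws scaled to the spike-in gave calls and 6 gave at least as many as observed; the number of draws was raised from 20 after sets of 20 had given unlike results. A list of 15 genes shifted by 0.5 was found by camera at its preset correlation (adjusted p = 8.04e-38) and missed with an estimated correlation (adjusted p = 0.131), and 0 of 25 unshifted lists passed. The simulations hold no correlation between genes other than the library noise. Alternatives were DESeq2 1.42.0, other scalings and filters, other spike-in factors, a block for the replicate number, an FDR of 0.01, glmTreat against 1.2-fold, leaving out each library, fry, and an estimated correlation in camera. Exonic length could not be used as an alternative, since the table used here holds 1 interval per gene.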

Results

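Nascent RNA was measured by TT-seq in HEK293 cells, an established human embryonic kidney line, of a degron line that had been transfected with RPB1, the largest subunit of RNA polymerase II. RPB1 ends in a C-terminal domain (CTD) built of repeats of a heptad in which tyrosine stands at position 1 and threonine at position 4. The transfected RPB1 carried either a 26x wild-type CTD or a 26x CTD with the substitutions Y1T and T4Y, which exchange these residues (below, the mutant). In TT-seq, cells take up 4-thiouridine for a short pulse, the RNA is fragmented, and the labelled fragments are purified, so that counts follow RNA made during the pulse. Here the cells were labelled with 1 mM 4-thiouridine for 20 min, and labelled yeast RNA was added at 1 part in 100 as a spike-in. Each group had 2 libraries. The human gene counts totalled 25781046 and 28183172 in the wild-type libraries and 21322531 and 23220986 in the mutant libraries. The yeast gene counts totalled 10496545 and 8368890 against 13339834 and 11067346. Whether the degron was triggered, and whether the replicates were separate cultures, is not given in the sources used here, so p-values measure the spread between these libraries, which may be technical.

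POLR2A, the gene of RPB1 itself (ENSG00000181222.19, hg38 chromosome 17, 7484366 to 7514616, plus strand), took the most counts of all human genes over the 4 libraries together. In both mutant libraries the mitochondrial rRNA gene RNR2 took more (250248 and 271857). POLR2A held 366557 and 330661 counts in the wild-type libraries and 207427 and 187885 in the mutant libraries. Relative to the other human genes it was lower in the mutant libraries by a log2 fold change of -0.57 (SE 0.0671, n = 2 per group, adjusted p = 1.05e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Scaled to the spike-in, its log2 fold change of -1.22 did not pass (edgeR adjusted p = 0.102). Counts from the cell's own gene and from the transfected copy are not separated by gene counting.

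The first question was whether the total amount of nascent RNA differed between the CTDs. Human RNA was lower against the yeast spike-in with the Y1T/T4Y CTD: 2.46 and 3.37 human counts per yeast count were found in the wild-type libraries and 1.598 and 2.098 in the mutant libraries. The means were 2.91 ± 0.645 and 1.85 ± 0.353 (SD, n = 2 each). On the log2 scale the mutant libraries differed by -0.65 (SE 0.301), which is 63.7% of the wild-type level. Within replicate numbers 1 and 2 the log2 difference was -0.62 and -0.68, so this SE may partly measure a shift shared by number. The labels do not say that equal numbers were handled together. The groups did not overlap, and the two-sided exact permutation p was 0.333, the smallest that 2 against 2 libraries can give. Within groups, replicate 2 lay 1.37 times above replicate 1 for the wild-type CTD and 1.31 times above it for the mutant, so replicates lay further apart than the nearest libraries of the groups (2.46 and 2.10).

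The mitochondrially encoded RNAs, which are made by the mitochondrial polymerase and not by RNA polymerase II, took 2.34% and 2.32% of human counts in the wild-type libraries and 2.94% and 3.03% in the mutant libraries (mean 2.33% ± 0.0147 against 2.99% ± 0.0672, SD, n = 2 each). Nuclear counts per mitochondrial count were 41.9 ± 0.270 with the wild-type CTD and 32.5 ± 0.754 with the mutant (SD, n = 2 each), a log2 difference of -0.37 (SE 0.0246), far larger than the spread between replicates (two-sided exact permutation p = 0.333, the smallest possible). Mitochondrial counts per yeast count overlapped between the groups, with a log2 difference of -0.29 (SE 0.311, two-sided exact permutation p = 0.667). Within replicate numbers 1 and 2 this difference was -0.2923 and -0.2964, so the overlap and the SE may also partly measure a shift shared by number.

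**Figure D1:**
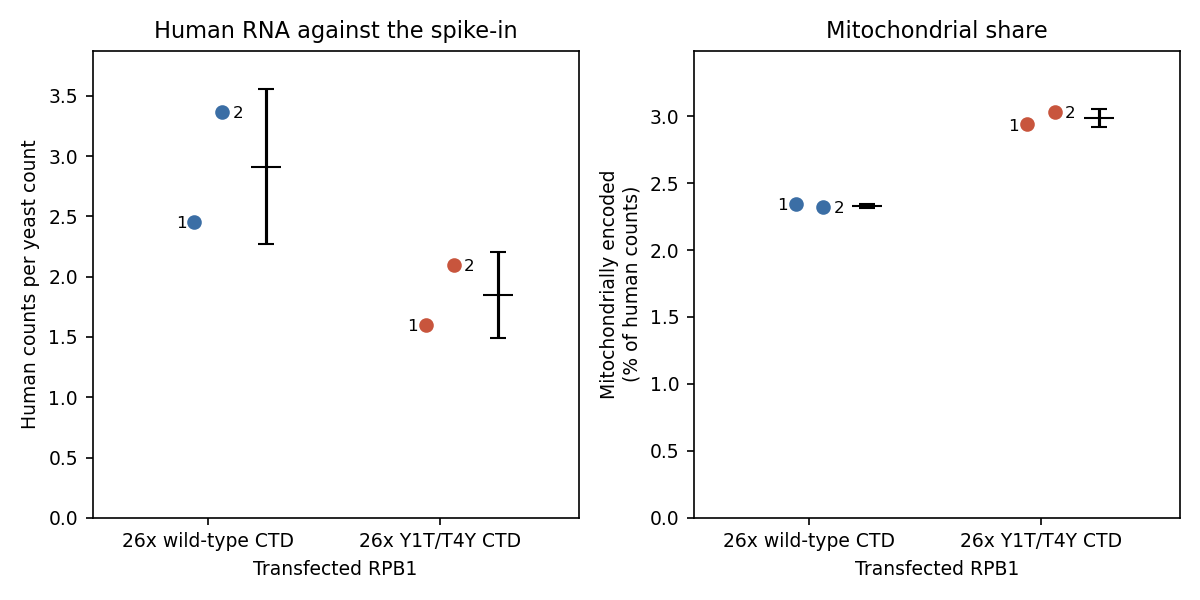
Human gene counts per yeast gene count (left) and mitochondrially encoded RNA as a percentage of human counts (right), 1 point per library numbered by replicate, with the mean and SD of 2 libraries beside them. Both mutant libraries lie below both wild-type libraries on the left (1.598 and 2.098 against 2.46 and 3.37) and above them on the right (2.94% and 3.03% against 2.34% and 2.32%).

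Scaled to the yeast spike-in, most genes sat lower in the mutant libraries, and the genes that passed the test all fell. The median log2 fold change over 24188 tested genes was -0.63, and 93.5% of genes lay below 0. At an FDR of 0.05, 625 genes were lower and 0 were higher by edgeR's quasi-likelihood test. There were 6760 genes at an unadjusted p under 0.05 in either direction. The largest falls among the named genes were those of ANKRD1, a stretch-responsive ankyrin-repeat gene (log2 fold change -2.85, adjusted p = 3.08e-08), LYPD1 (-2.45, adjusted p = 0.000478), ANXA1, which encodes annexin A1 (-2.34, adjusted p = 2.10e-06), and TMEM144 (-2.34, adjusted p = 4.98e-05). MYC, the growth-promoting transcription factor, fell by 2.29 on the log2 scale (edgeR adjusted p = 2.97e-05), and EGR1 fell by 1.81 (edgeR adjusted p = 0.00341). The count depended on single libraries: 50 and 21 genes were lower without wild-type replicate 1 or 2, and 5 and 2 without mutant replicate 2 or 1. DESeq2 called 6458 lower and 0 higher, yeast totals without TMM gave 372 lower, and no filter on low counts gave 321. All genes share the same scaling error of each library, and in simulated counts with no gene changed and the observed spread of the ratio, 10 of 100 draws gave calls and 6 gave at least as many as observed. The draws took the noise of each library as independent and changed no gene against the others. If part of the noise is shared by replicate number, they do not give the chance rate for these data.

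The second question was which genes moved against the rest of the human library, which is free of the spike-in. In this fit 607 genes were higher and 1438 lower in the mutant libraries out of 24188 tested (edgeR, FDR 0.05), with 5261 genes at an unadjusted p under 0.05. The called genes changed by a median log2 fold change of 0.46 when higher and -0.43 when lower. Changes of at least 2-fold were seen for 61 genes that rose and 100 that fell. Of the 625 genes that fell against the spike-in, 523 also fell here. Among protein-coding genes, 1163 of 13300 tested fell and 329 rose, whereas among lncRNA genes 71 of 2513 rose and 38 fell. Of the calls 70.3% were falls. Upper-quartile scaling, under which the median of all genes was 0.08 instead of 0.02, gave 1025 higher and 935 lower (47.7% falls). DESeq2 gave 293 higher and 1217 lower. Without wild-type replicate 1 or 2 the counts were 375 and 1522 higher and 1216 and 2584 lower, and without mutant replicate 1 or 2 they were 209 and 115 higher and 634 and 511 lower.

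The genes with the largest falls were ANKRD1, LYPD1, RNVU1-22, ANXA1, TMEM144, MYC, RNU2-63P and CDH26. ANKRD1 (ENSG00000148677.7, chromosome 10, 90912096 to 90921087, minus strand) went from 9.18 ± 2.08 CPM (TMM-scaled counts relative to library size) to 1.96 ± 0.12 (SD, n = 2 each), a log2 fold change of -2.22 (SE 0.227, edgeR adjusted p = 8.41e-08). MYC (ENSG00000136997.21, chromosome 8, 127735434 to 127742951, plus strand) went from 105 ± 41.6 to 32.8 ± 4.30 CPM, a log2 fold change of -1.68 (SE 0.145, edgeR adjusted p = 9.13e-09). ANXA1 (ENSG00000135046.14, chromosome 9, 73151865 to 73170393, plus strand) went from 36.7 ± 10.7 to 11.2 ± 1.44 CPM, a log2 fold change of -1.72 (SE 0.151, edgeR adjusted p = 1.07e-08). CDH26, a cadherin, fell by 1.59 on the log2 scale, TMEM144 by 1.69 and LYPD1 by 1.83. RNVU1-22 fell by 1.74 and RNU2-63P by 1.61; these belong to the multicopy families of the U1 and U2 spliceosomal RNAs, and near-identical copies make their counts uncertain. Of these 8 genes only LYPD1 lost its call with a library left out, without wild-type replicate 1 (edgeR adjusted p = 0.0617).

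The genes with the largest rises were all weakly expressed, at a mean of 9.12 CPM or less in the mutant libraries. LINC02660, a long noncoding RNA gene (ENSG00000226005.5, chromosome 10, 3911889 to 3935817, plus strand), went from 0.929 ± 0.214 to 2.80 ± 0.270 CPM (SD, n = 2 each), a log2 fold change of 1.58 (SE 0.337, edgeR adjusted p = 0.00235). SLC9C2, of the sodium-proton exchanger family (ENSG00000162753.13, chromosome 1, 173500460 to 173603072, minus strand), went from 3.78 ± 0.616 to 9.12 ± 0.526 CPM, a log2 fold change of 1.27 (SE 0.195, edgeR adjusted p = 5.02e-05). The homeobox gene TLX3 rose by 1.27 on the log2 scale, the noncoding genes LINC01586, DNPEP-AS1 and DENND6A-DT by 1.28, 1.23 and 1.22, the 5S rRNA pseudogene RNA5SP177 by 1.37, and F13A1, the A chain of coagulation factor XIII, by 1.18. Under the spike-in scaling none of these 8 genes passed. The calls of LINC02660, SLC9C2 and DENND6A-DT held with each library left out, and the other 5 lost theirs. These were RNA5SP177 without mutant replicate 1 or 2, LINC01586 without wild-type replicate 2, TLX3 without mutant replicate 1, and DNPEP-AS1 and F13A1 without wild-type replicate 1 or mutant replicate 1, with edgeR adjusted p of up to 0.0692, 0.12, 0.0601, 0.289 and 0.393.

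**Figure D2:**
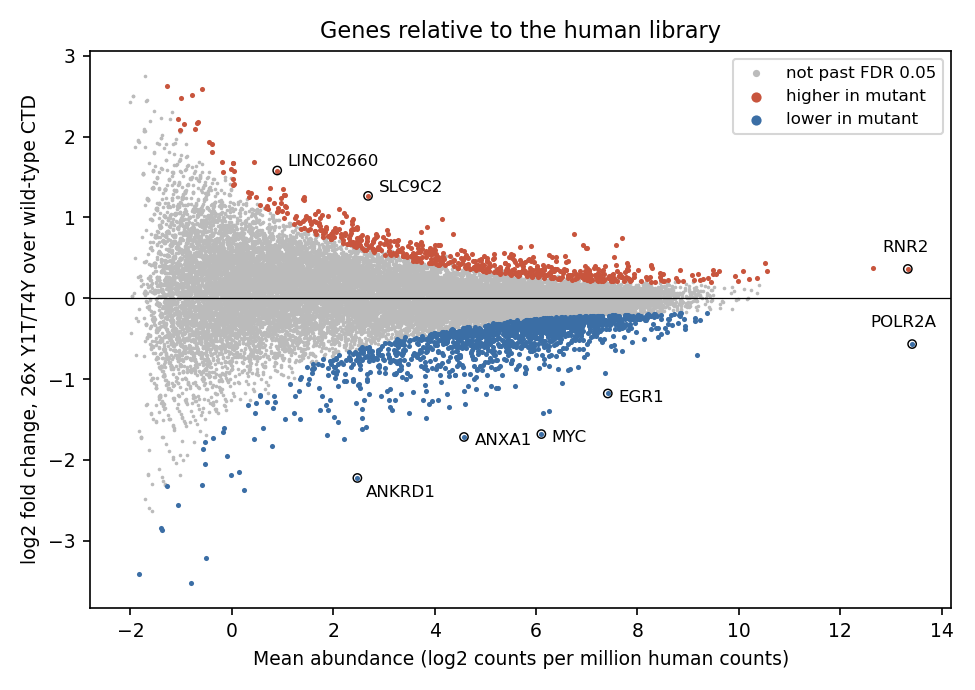
Each point is 1 of 24188 tested genes: mean abundance over the 4 libraries (x axis, log2 CPM of human counts) against the log2 fold change of the 26x Y1T/T4Y CTD over the 26x wild-type CTD (y axis), coloured where the gene passed an FDR of 0.05. The 607 higher genes reach large folds at low abundance, and POLR2A (-0.57) and RNR2 (0.36) lie at the right edge.

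Gene lists fixed before the data were examined were tested for a joint shift relative to the other genes. Immediate early genes, which respond within minutes to growth signals, changed in both directions: of 42 tested members 8 fell and 4 rose, and 10 fell and 8 rose when adjusted over the list alone. EGR1 (ENSG00000120738.8, chromosome 5, 138465479 to 138469303, plus strand) went from 237 ± 36.7 to 105 ± 2.06 CPM (SD, n = 2 each), a log2 fold change of -1.18 (SE 0.0789, edgeR adjusted p = 5.34e-11). MYC fell by 1.68 on the log2 scale, ARC by 1.42, TRIB1 by 1.39 and the nuclear receptor gene NR4A1 by 0.69. FOSB rose by 0.51 and FOSL1, also of the AP-1 family, by 0.31. The list as a whole was shifted down by camera with its preset correlation (adjusted p = 0.0103). Its median was -0.02, which turned to 0.003 under total-count and 0.04 under upper-quartile scaling, and the adjusted p was 0.76 with an estimated correlation and 0.197 over genes with at least 50 counts. Without wild-type replicate 2, 13 members fell, and without mutant replicate 1 or 2 only 2 rose.

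Genes for ribosome biogenesis were shifted down together: 7 of 26 tested members fell and 0 rose, and 11 fell when adjusted over the list alone (camera adjusted p = 0.000132; adjusted p = 0.76 with an estimated correlation). The median log2 fold change was -0.16. POLR1A, the largest subunit of RNA polymerase I, went from 126 ± 4.01 to 100.5 ± 0.534 CPM (SD, n = 2 each; log2 fold change -0.32, SE 0.0699, edgeR adjusted p = 0.00294). WDR43, a factor of the small-subunit processome, had a log2 fold change of -0.26 (edgeR adjusted p = 0.00613; 0.0705 with upper-quartile scaling), and NPM1, UTP20, TCOF1, NAT10 and PES1 fell by 0.24 to 0.28. None of the members passed without mutant replicate 1 or without mutant replicate 2, whereas camera still placed the list lower in both (adjusted p = 0.000109 and 0.00349).

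The replication-dependent histone genes, whose transcripts are not polyadenylated and are made in S phase, were also shifted down. Of 29 tested members 7 fell and 0 rose, and 8 fell when adjusted over the list alone, but 4 by DESeq2 (median log2 fold change -0.25; camera adjusted p = 0.00015; adjusted p = 0.76 with an estimated correlation). H3C1 went from 18.7 ± 4.23 to 10.1 ± 0.649 CPM (SD, n = 2 each; log2 fold change -0.89, SE 0.154, edgeR adjusted p = 0.000241), and the linker histone gene H1-2 from 54.2 ± 12.5 to 34.7 ± 2.32 CPM (log2 fold change -0.64, SE 0.113, edgeR adjusted p = 0.000262). H1-4, H3C13, H3C2, H1-3 and H2AC13 fell by 0.67, 0.94, 0.74, 1.43 and 0.98 on the log2 scale. The spliceosomal RNA genes transcribed by RNA polymerase II moved the same way: 6 of 14 tested members fell and 0 rose, and 6 fell when adjusted over the list alone (median log2 fold change -0.56; camera adjusted p = 0.00015; adjusted p = 0.76 with an estimated correlation). RNVU1-27, a U1 variant, went from 29.7 and 22.0 CPM to 13.2 and 13.4 CPM (log2 fold change -0.96, edgeR adjusted p = 2.06e-05), and RNVU1-7 and RNU5F-1 fell by 1.12 and 1.02, with the multicopy uncertainty named above. Both lists rested on wild-type replicate 1: without it 4 histone and 2 spliceosomal RNA genes fell, and camera gave adjusted p of 0.427 and 0.454. Without wild-type replicate 2, 12 histone genes fell, and without mutant replicate 1, 3 spliceosomal RNA genes fell.

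RNAs made by other polymerases moved the opposite way relative to the human library. The list of mitochondrially encoded genes holds protein-coding and rRNA genes but no tRNA genes. Of its 15 members 14 rose and 0 fell, with 14 also adjusted over the list alone (camera adjusted p = 1.9e-14, and 0.76 with an estimated correlation). The member ND6 did not pass, at a log2 fold change of 0.03 (edgeR adjusted p = 0.834). Over all 28 tested genes of the mitochondrial genome, 15 rose and 0 fell, so most of those outside the list did not pass. The preset correlation takes the members as nearly independent, which genes of the same mitochondrial genome need not be. The median log2 fold change of the 15 genes was 0.29, and it was -0.36 under the spike-in scaling. The mitochondrial rRNA genes RNR2 and RNR1 had log2 fold changes of 0.36 (SE 0.0473, edgeR adjusted p = 4.84e-06) and 0.38 (SE 0.0495, edgeR adjusted p = 5.49e-06), and COX1 and COX3 rose by 0.34 and 0.35. The RNA polymerase III transcripts had a median log2 fold change of 0.34, and of -0.29 under the spike-in scaling: 2 of 17 tested members rose and 0 fell, and 4 rose when adjusted over the list alone (camera adjusted p = 0.00492; adjusted p = 0.76 with an estimated correlation). RN7SL1, the RNA of the signal recognition particle, went from 486 ± 32.9 to 591 ± 11.9 CPM (SD, n = 2 each; log2 fold change 0.28, edgeR adjusted p = 0.00279), and RNY1, a Y RNA, from 17.7 ± 0.290 to 25.9 ± 1.85 CPM (log2 fold change 0.55, edgeR adjusted p = 0.00306). Without mutant replicate 1 or 2, 9 and 2 mitochondrial genes rose, and 1 and 0 polymerase III transcripts did. The camera call of the latter was lost without mutant replicate 2 (adjusted p = 0.0997) and without wild-type replicate 2 (adjusted p = 0.0783). RN7SL1 lost its call without mutant replicate 1 or 2 and RNY1 without mutant replicate 2, with edgeR adjusted p of up to 0.151 and 0.169.

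**Figure D3:**
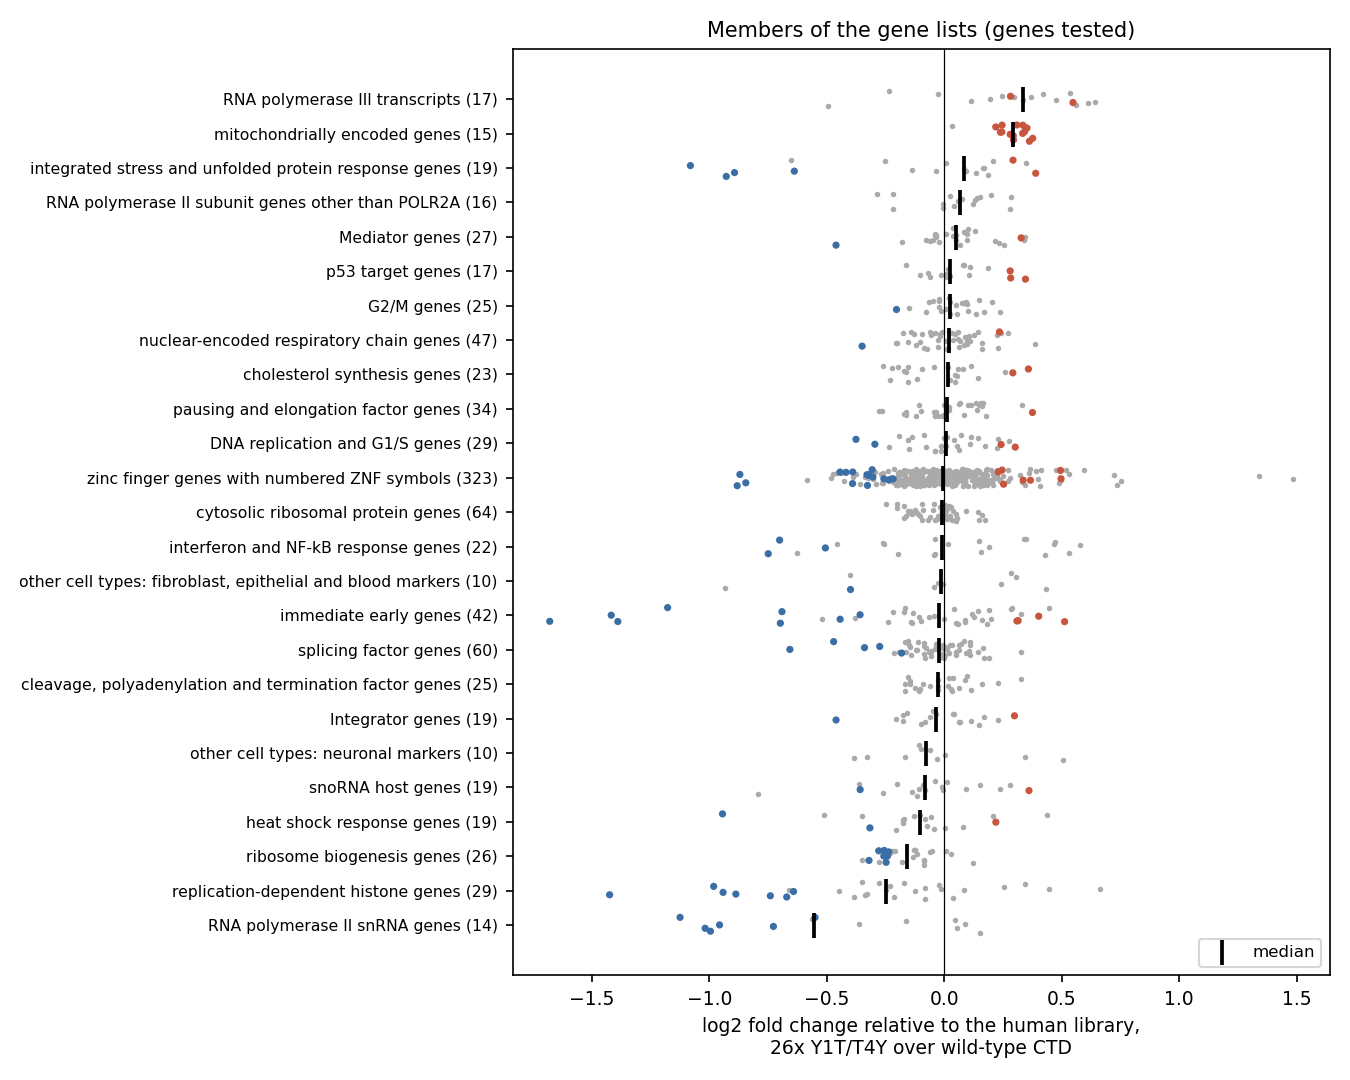
Members of the 25 gene lists with at least 3 tested genes, as log2 fold change of the 26x Y1T/T4Y CTD over the 26x wild-type CTD relative to the human library (x axis). Points are genes, coloured where they passed an FDR of 0.05 (red higher, blue lower), bars are medians and the number of tested genes stands after each name; the polymerase III and mitochondrial lists lie highest (medians 0.34 and 0.29, and -0.29 and -0.36 under the spike-in scaling) and the RNA polymerase II snRNA genes lowest (-0.56).

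Lists of the transcription machinery itself held from 0 to 5 calls each. Among 16 other subunit and assembly genes of RNA polymerase II, 0 passed by edgeR over all genes or by DESeq2, 5 had an unadjusted p under 0.05, and 2 were higher and 2 lower when adjusted over the list alone. RPAP2, a CTD phosphatase, and POLR2C had log2 fold changes of -0.22 and 0.28 (edgeR adjusted p = 0.0539 and 0.0598). Of 27 Mediator genes MED29 rose by 0.33 and MED12L fell by 0.46 on the log2 scale, and adjusted over the list alone 2 rose and 1 fell. Of 19 Integrator genes INTS6L rose by 0.30 and INTS10 fell by 0.46, and adjusted over the list alone 1 rose and 2 fell; by DESeq2 0 rose and 2 fell, and INTS6L lost its call by DESeq2 and with no filter on low counts (adjusted p = 0.0693 and 0.0522). Among 34 pausing and elongation factor genes HEXIM1, the inhibitor of P-TEFb, rose by 0.38 (edgeR adjusted p = 0.00279), the only call over all genes and adjusted over the list alone, and EAF2 had a log2 fold change of 0.33 (edgeR adjusted p = 0.061). Among 25 cleavage, polyadenylation and termination factor genes 0 passed by edgeR in either adjustment or by DESeq2, 4 had an unadjusted p under 0.05, and TOX4 and CPSF6 had log2 fold changes of 0.23 and -0.16. Of 60 splicing factor genes 5 fell and 0 rose, and 6 fell adjusted over the list alone; HNRNPR went from 213 ± 16.6 to 154 ± 0.659 CPM (SD, n = 2 each; log2 fold change -0.47, edgeR adjusted p = 2.06e-05) and HNRNPA3 fell by 0.34. Without wild-type replicate 2, 12 splicing factor genes fell and 2 rose, and without mutant replicate 1 or 2 only 1 fell. Leaving out wild-type replicate 2 also gave 5 rises and 2 falls among the pausing and elongation factors, 1 and 4 among the 3' end factors, 3 and 1 in Mediator, 3 and 2 in Integrator and 2 and 1 among the polymerase subunits. Without wild-type replicate 1 there were 1 and 3, 0 and 0, 1 and 2, 0 and 2, and 0 and 2 in the same order. Without mutant replicate 1 there were 1 and 0, 0 and 0, 0 and 1, 0 and 0, and 0 and 0, and without mutant replicate 2 only 1 fall in Mediator and 1 in Integrator. None of these 6 lists was shifted as a whole by camera (adjusted p from 0.247 to 0.847). MED12L and HNRNPR kept their calls with each library left out. HEXIM1 lost its call without mutant replicate 2, INTS10 without mutant replicate 1, HNRNPA3 without either mutant library, and MED29 and INTS6L without wild-type replicate 1 or either mutant library, with edgeR adjusted p of up to 0.126, 0.0645, 0.0938, 0.258 and 0.335.

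Stress and metabolic lists held single genes with clear changes in mixed directions. In the list of the integrated stress and unfolded protein responses, 4 of 19 tested genes fell and 2 rose, over all genes and adjusted over the list alone; its median was 0.08, its mean -0.13, and camera placed it lower without passing (adjusted p = 0.327). PSAT1, an enzyme of serine synthesis, went from 215 ± 29.9 to 113 ± 2.90 CPM (SD, n = 2 each; log2 fold change -0.93, SE 0.0767, edgeR adjusted p = 5.72e-09), and SLC7A11, the cystine transporter, from 65.7 ± 14.6 to 31.03 ± 1.77 CPM (log2 fold change -1.08, SE 0.110, edgeR adjusted p = 8.41e-08). Of 19 heat shock genes 2 fell and 1 rose, and 6 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.0848; 0.0117 without wild-type replicate 2 and 0.038 without mutant replicate 2; over all libraries adjusted p = 0.76 with an estimated correlation); HSPA1B fell by 0.94 and HSPA8 by 0.32, and 6 members fell without wild-type replicate 2, 3 without wild-type replicate 1 and 1 without mutant replicate 1. Of 17 p53 target genes 3 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.249), with CDKN1A, the p21 cell-cycle inhibitor, at a log2 fold change of 0.35 (edgeR adjusted p = 0.00179) and DDB2 at 0.28 (edgeR adjusted p = 0.0223). Of 23 cholesterol synthesis genes HMGCS1 and IDI1 rose by 0.29 and 0.36 and 0 fell, also adjusted over the list alone (median 0.02, mean -0.01, camera adjusted p = 0.98). Without wild-type replicate 2, however, 4 cholesterol genes fell and 2 rose, without wild-type replicate 1 only 1 rose, and without either mutant library none passed by edgeR. The p53 list held 1 and 4 rises without wild-type replicate 1 or 2, and 0 and 1 without mutant replicate 1 or 2. The stress response list held 6 falls without wild-type replicate 2 and 0 rises without either mutant library. PSAT1, SLC7A11 and HSPA1B kept their calls with each library left out. HSPA8 and CDKN1A lost theirs without mutant replicate 1, HMGCS1 without either mutant library, and DDB2 and IDI1 without wild-type replicate 1 or either mutant library, with edgeR adjusted p of up to 0.302, 0.156, 0.357, 0.277 and 0.258.

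The remaining lists were not shifted by camera (adjusted p from 0.496 to 0.847). None of 64 cytosolic ribosomal protein genes passed by edgeR, over all genes or adjusted over the list alone, or by DESeq2, with 8 at an unadjusted p under 0.05 and RPL10A and RPS2 at log2 fold changes of -0.20 and 0.16; without wild-type replicate 2, however, 18 fell (camera adjusted p = 0.000257; over all libraries adjusted p = 0.882 with an estimated correlation), and without wild-type replicate 1, 3 rose. Of 19 snoRNA host genes SNHG1 fell by 0.36 and SNHG31 rose by 0.36, also adjusted over the list alone. Of 29 DNA replication and G1/S genes 2 rose and 2 fell, or 3 and 2 adjusted over the list alone and 1 and 2 by DESeq2, with MCM3 and UNG falling by 0.30 and 0.38. Of 25 G2/M genes CENPF fell by 0.21 and 0 rose, and 0 passed adjusted over the list alone; CENPF lost its call with total counts, with upper-quartile scaling and over genes with at least 50 counts (edgeR adjusted p = 0.0719, 0.208 and 0.054), and CDC25C had a log2 fold change of 0.24 (edgeR adjusted p = 0.0656). Of 22 interferon and NF-kB genes 3 fell and 0 rose, or 3 and 1 adjusted over the list alone, with IFIH1 and RELB falling by 0.70 and 0.51; by DESeq2 1 fell, and RELB lost its call by DESeq2, with total counts and with upper-quartile scaling (adjusted p = 0.064, 0.0567 and 0.0646). Of 47 nuclear-encoded respiratory chain genes NDUFS4 fell by 0.35 and ATP5F1B rose by 0.24, also adjusted over the list alone. Of 323 numbered ZNF genes 16 fell and 7 rose, or 16 and 5 adjusted over the list alone and 14 and 3 by DESeq2, with a median of -0.005 and a mean of 0.002; ZNF618 fell by 0.88 and ZNF678 by 0.39, and without wild-type replicate 2, 38 fell and 23 rose, against 7 and 3 falls and 1 and 0 rises without mutant replicate 1 or 2, and 14 falls and 1 rise without wild-type replicate 1. Of these genes ZNF618 and ZNF678 kept their calls with each library left out, and SNHG1, SNHG31, MCM3, UNG, CENPF, IFIH1, RELB, NDUFS4 and ATP5F1B each lost theirs without at least 1 mutant library, with edgeR adjusted p of up to 0.42, 0.276, 0.258, 0.34, 0.488, 0.281, 0.466, 0.188 and 0.395. In the same order of lists, without wild-type replicate 2 there were 1 rise and 3 falls (snoRNA host), 5 and 3 (replication), 3 and 2 (G2/M), 0 and 4 (interferon), and 2 and 3 (respiratory chain). Without wild-type replicate 1 there were 0 and 1, 2 and 3, 0 and 1, 0 and 0, and 1 and 2. Without mutant replicate 1 or 2 these lists held 0 rises and at most 1 fall each. Among markers of other cell types, 0 of 10 neuronal markers passed by edgeR, over all genes or adjusted over the list alone, or by DESeq2, with 1 at an unadjusted p under 0.05 and GAP43 and SYT1 at -0.38 and -0.11 (edgeR adjusted p = 0.156 and 0.362). Of 10 fibroblast, epithelial and blood markers KRT8 fell by 0.40, also adjusted over the list alone, and lost its call without wild-type replicate 1 or mutant replicate 2 (edgeR adjusted p of up to 0.361) and by DESeq2. In this list 2 fell without wild-type replicate 2 or mutant replicate 1, and 1 neuronal marker fell without wild-type replicate 2. KRT18 stood at -0.40 (edgeR adjusted p = 0.108). KRT8 and KRT18 overlap on opposite strands.

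**Figure D4:**
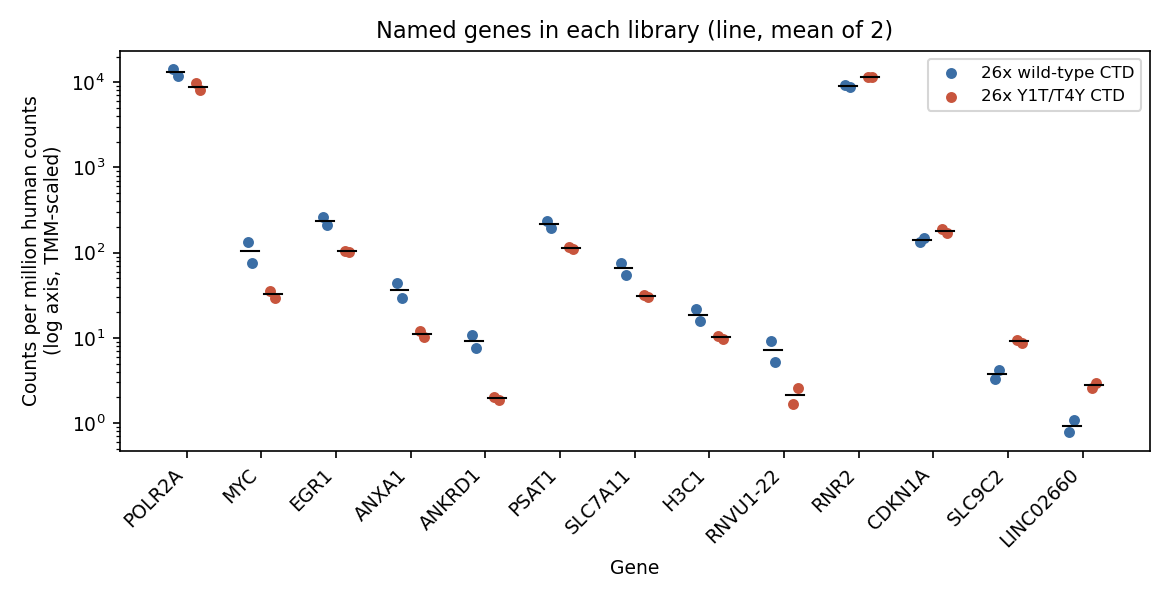
CPM of human counts (log axis, TMM-scaled) of 13 named genes in each of the 4 libraries, with points for libraries and lines for the mean of 2. MYC, EGR1, ANXA1, ANKRD1, PSAT1, SLC7A11, H3C1 and RNVU1-22 lie lower in both mutant libraries, and RNR2, CDKN1A, SLC9C2 and LINC02660 higher relative to the human library.

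The make-up of the labelled RNA shifted slightly. Protein-coding genes took 82.62% and 82.72% of human counts in the wild-type libraries and 81.70% and 81.59% in the mutant libraries (82.67% ± 0.0659 against 81.65% ± 0.0766, SD, n = 2 each), and lncRNA genes 2.20% ± 0.0203 against 2.29% ± 0.0154. RNA polymerase III transcripts took 0.0586% ± 0.00452 against 0.0729% ± 0.000674, and RNA polymerase II snRNA genes 0.0180% ± 0.00419 against 0.0145% ± 0.00154, which overlapped between the groups. The two-sided exact permutation p was 0.333 for 6 of the 7 classes, the smallest possible, and 0.667 for the snRNA genes (Benjamini-Hochberg adjusted 0.389 and 0.667). Without the 10 genes with the most counts the difference of protein-coding genes was -0.48 percentage points instead of -1.02, and that of mitochondrially encoded genes 0.122 instead of 0.655. These 10 genes include POLR2A and the mitochondrial genes RNR2, RNR1, COX1, ND5 and ND4, so part of both differences was taken out with them.

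Change was compared with gene length, since an altered CTD could affect elongation over long genes. Across 24188 genes, which are not independent replicates, Spearman's rho between length and log2 fold change was -0.07 (Pearson's r -0.05). It ran from -0.16 to 0.02 over the 4 pairs of a mutant with a wild-type library, and it was 0.09 and 0.13 between the replicates of the wild-type and the mutant group. The rho of the fit was thus smaller in size than those between replicates, while that of mutant replicate 1 over wild-type replicate 2 (-0.16) was larger. The median log2 fold change was 0.07 in the shortest genes (bin 1 of 5, 49 to 8324 bp) and 0.000663 in the longest (bin 5, 100175 bp and above). Calls were unevenly spread over length: 67 of the 4838 shortest genes fell and 96 rose, against 619 and 172 of the 4838 longest. The longest genes were not shifted down as a group (quartiles -0.173 and 0.193). Introns are counted with exons, so longer genes can gather more counts and be called more easily, which was not tested. Easier calling by itself has no direction, whereas falls grew from 67 to 619 and rises only from 96 to 172. It need not account for the excess of falls among long genes.

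Genes lying behind an active gene were examined because a gene count takes up transcription that runs past the end of the gene before. For 2416 tested genes that start within 10 kb behind a same-strand gene of at least 2 times their mean CPM, the median log2 fold change was 0.01, against 0.09 for 10000 random gene lists matched on expression, below all of them. The difference of -0.07 was negative in each of the 4 pairs of a mutant with a wild-type library, and 43 of these genes rose and 56 fell by edgeR. Between replicates the list stood at percentile 100 in the wild-type group and 2.67 in the mutant group, so lists of this size also depart from random lists without a change of CTD. The differences there were 0.0299 and -0.0134, against -0.0277 to -0.0771 over the 4 pairs of a mutant with a wild-type library. The difference was -0.02 within 50 kb and -0.10 behind genes of at least 10 times the CPM.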

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

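The tests on the spike-in shift and on the yeast gene, and for lncRNA genes the comparisons at matched counts per kilobase and matched expression, were chosen after the results or closely related values were seen; the thinning test was written before its result, and what thinning moved was looked up after it.

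In the yeast spike-in, which served only as a scale, the gene YDL140C (RPO21, the yeast RPB1) stood out as a signal outside the human measurement: its level was 7.02 times higher in the wild-type than in the mutant libraries (108730 and 90270 counts against 20445 and 16932; log2 change -2.81, SE 0.0321, edgeR adjusted p = 1.07e-19). A general difference between the yeast RNA added to the groups is argued against, since 0.265% of 6034 tested yeast genes changed. YOR151C, the yeast RPB2, stood at -0.02. All 16 that changed were however lower in the mutant libraries, and 10 of them over 2-fold. These included YLR154W-C (5.22-fold), YLR154W-E (4.27-fold) and YAL004W (11.2-fold, 26 and 43 counts against 4 and 4). For YDL140C, human reads falling on yeast genes in proportion to human counts are argued against, because the log2 human to yeast ratio changed by only -0.65. For the other changed genes this was not tested. A candidate explanation is that reads of the transfected 26x wild-type CTD align to the yeast gene; the titles of these libraries carry the label yCTD, whose meaning and the construct's sequence are not given in the sources used here. The counts above the mutant level had a ratio of 0.927 between the wild-type libraries per POLR2A count and of 1.05 per yeast count. POLR2A counts (366557 and 330661) and yeast counts (10496545 and 8368890) both fell from wild-type replicate 1 to 2 by similar factors. The 2 ratios therefore had to lie close together. Near equality the test could not have told this explanation from a steady share of yeast counts, so it decides nothing. The first bound for this test, 5% around equality, would have counted against the explanation. It was widened to 1.5-fold after both ratios had been seen, because POLR2A counts mix the cell's own and transfected RNA. The explanation stays open, and with and without this gene and the YLR154W genes in a TMM-adjusted yeast scale the human to yeast difference was -0.67, an alternative added after the data were seen.

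Human counts were lower against the spike-in in both mutant libraries. An unequal amount of spike-in would move nuclear and mitochondrial counts alike. It is argued against as the cause of the change in their log2 ratio, which differed by -0.3665 (SE 0.0246). This ratio holds no yeast counts and does not tell a fall of nuclear counts from a rise of mitochondrial counts. It therefore does not decide how much of the fall against yeast came from the spike-in. For the shift of mitochondrial counts against yeast (-0.2944, SE 0.311), an unequal spike-in and a real fall cannot be told apart, because both would move this ratio and 2 libraries per group overlap. Unlabelled cytoplasmic RNA carried through the purification might also raise the mitochondrial share; cytosolic ribosomal protein genes, whose mRNAs are abundant and stable, stood 0.0202 above matched random lists (percentile 79.8), which decides neither way. A lower output of RNA polymerase II with the Y1T/T4Y CTD remains open beside these. POLR2A counts, own and transfected together, were also lower in the mutant libraries relative to the other human genes (log2 fold change -0.57). An effect of the CTD sequence is therefore not separated from one of the amount of RPB1 RNA.

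The lncRNA genes sat higher than protein-coding genes in the mutant libraries relative to the human library, with medians of 0.15 over 2513 lncRNA genes and -0.02 over 13300 protein-coding genes, a difference of 0.17 (0.161 to 0.189 with each library left out). A trend with expression shared by both classes is argued against as the whole cause, since lncRNA genes stood 0.0918 above protein-coding genes of the same mean expression (0.0586 to 0.118 with each library left out), but it may be a part: in the 3 lowest of 10 expression bins the medians were 0.172, 0.156 and 0.151 for lncRNA genes (437, 455 and 403 genes) and 0.12, 0.167 and 0.141 for protein-coding genes, against 0.215 and 0.0796 in bin 4, 0.191 and 0.0273 in bin 5, 0.152 and -0.025 in bin 6, 0.0819 and -0.0436 in bin 7, 0.0478 and -0.0604 in bin 8, -0.0288 and -0.0447 in bin 9 and 0.00693 and -0.0197 in bin 10. Fewer human counts in the mutant libraries are argued against only as far as they act through the filter or through low counts. The difference was 0.17 after the wild-type libraries were thinned to the mean mutant depth (22271850 and 22270090 counts). Thinning took 496 genes below the filter and the calls from 607 higher and 1438 lower to 532 and 1340. It keeps the expected share of every gene (median movement of lncRNA genes -0.0027), so it does not decide on other effects of depth. A background of reads spread evenly over the genome is argued against as the whole cause, since lncRNA genes stood 0.146 above protein-coding genes with the same counts per kilobase, but it may still be a part, as protein-coding genes had a median of 0.15 where counts per kilobase were lowest and 0.01 where they were highest, each over 1 of 5 bins. For the rest of the gap a different response of lncRNA genes to the Y1T/T4Y CTD remains open.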

How the results depend on the processing

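Only the alternatives that leave YDL140C and the YLR154W genes out of the yeast factor, or POLR2A out of the human counts, were chosen after the data were seen. Of 188 values under settings that keep all libraries, 155 stayed the same, and of 156 values with a library left out, 138 did. Same means for a test the same side of the threshold and, for a call, the same direction, for a count of genes within 1.5 times the count reported, and for a value without a test a shift under 1 SD between replicates or, for length and neighbours, between the 4 comparisons of 1 mutant with 1 wild-type library. The human to yeast log2 difference lay between -0.88 and -0.42 with each library left out, always below 0. Where a library is left out, the lone library is assumed to vary like the others. Depth limits weakly expressed genes, and 2 libraries per group limit every p. Exonic length was not run as an alternative. The cause of the changes below was not tested, except that a stricter FDR or a minimum fold calls fewer genes by construction; of the genes named by rule that passed with a log2 fold change under 0.5 in size, only HNRNPR passed glmTreat.

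Scaled to the spike-in, the number of lower genes was 6458 by DESeq2, 321 with no filter on low counts, 372 with yeast totals, 150 at an FDR of 0.01, 258 by glmTreat against 1.2-fold and from 2 to 50 with a library left out. Relative to the human library, higher and lower genes were 293 and 1217 by DESeq2, 1025 and 935 with upper-quartile scaling, 195 and 811 at an FDR of 0.01, 34 and 322 by glmTreat, and from 115 to 1522 and from 511 to 2584 with a library left out. With the replicate number as a block, 18 genes were higher and 15237 lower against the spike-in, and 1459 higher and 2345 lower relative to the human library. The labels do not say that equal numbers share a culture or day, and over genes the deviations of same-numbered libraries correlated at 0.053. The numbers were therefore not taken to pair the libraries. A correlation over genes cannot show a shift that a whole library shares. Principal component 2 (27.996% of variance) separated the numbers, and within numbers 1 and 2 the log2 difference was -0.62 and -0.68 for human to yeast and -0.29 and -0.30 for mitochondrial to yeast counts, as hints from the data that the spike-in ratio may share a shift by number. The SEs and the simulated library noise take the libraries as independent.

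With an estimated correlation camera gave adjusted p of 0.7598 for the mitochondrial, ribosome biogenesis, histone, snRNA, RNA polymerase III and immediate early lists. Fry, which asks whether a list moves one way on balance and does not compare it with other genes, gave 0.191 for the mitochondrial and ribosome biogenesis lists, 0.6091 for the histone and immediate early lists, 0.6269 for the snRNA list and 0.2716 for the polymerase III list. The immediate early list gave 0.1973 over genes with at least 50 counts in 2 libraries. With each library left out, camera's adjusted p ran from 8.39e-09 to 0.427 (histone), 2.02e-07 to 0.454 (snRNA), 0.000404 to 0.0997 (polymerase III), 0.000257 to 0.636 (ribosomal protein) and 0.0117 to 0.237 (heat shock). The difference of downstream neighbours was -0.0244 within 50 kb and -0.0994 behind genes of at least 10 times the CPM. Without the 10 genes with the most counts, among them POLR2A, RNR2 and RNR1 of these same classes, the class differences were 0.122 (mitochondrial) and -0.4798 (protein-coding) percentage points. Against the spike-in, where none of these genes passed, the log2 fold change changed sign for F13A1 without wild-type replicate 1 and for RNY1, SNHG31, CDKN1A, IDI1, HEXIM1 and EAF2 without wild-type replicate 2, and for RNY1 also without mutant replicate 1. With each library left out it ran from -0.04216 to 1.198 (F13A1), -0.3872 to 0.1485 (RNY1), -0.595 to 0.06598 (SNHG31), -0.5965 to 0.008552 (CDKN1A), -0.6414 to 0.1191 (IDI1), -0.6196 to 0.1369 (HEXIM1) and -0.6711 to 0.1045 (EAF2).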

Other observations

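The synthetase test below was written before its own result was seen, but the idea for it came from looking through the genes with the lowest p, families of gene names and counts per chromosome; no other list was added.

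Several genes with clear falls belong to no list of the report; they, like the other genes of this part, were chosen after their values were seen. Relative to the human library, BCAT1, a branched-chain aminotransferase, had a log2 fold change of -1.05 (SE 0.089, edgeR adjusted p = 6.89e-09), ASS1, argininosuccinate synthase, of -1.30 (SE 0.149, adjusted p = 6.45e-07), XPOT, the tRNA exporter, of -0.73 (adjusted p = 3.57e-07), MTHFD1L, of mitochondrial folate metabolism, of -0.65 (adjusted p = 3.53e-07) and ALDH18A1, of proline synthesis, of -0.65 (adjusted p = 1.25e-06), beside PSAT1 and SLC7A11. ATF4, the transcription factor that drives many such genes, stood at -0.14 (adjusted p = 0.329), and the transporter genes SLC7A5 and SLC3A2 at -0.04 and 0.01 (adjusted p = 0.792 and 0.934). SHMT2, of mitochondrial serine and folate metabolism like MTHFD1L, stood at 0.07 (adjusted p = 0.781).

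From part of these genes came the hypothesis of a joint fall of genes for amino acid supply. It was tested on the cytosolic aminoacyl-tRNA synthetase genes in the same libraries, so the test is not independent of the search. Of 19 tested members 8 fell and 0 rose by edgeR, and 9 fell and 1 rose when adjusted over the list alone, with a median log2 fold change of -0.17 and 16 members below 0. IARS1, GARS1, EPRS1 and AARS1 fell by 0.37, 0.42, 0.43 and 0.44 on the log2 scale, and KARS1 stood at 0.20 (edgeR adjusted p = 0.086). Camera gave p = 2.36e-06 at the preset correlation and between 2.96e-08 and 0.000146 with each library left out; with an estimated correlation p was 0.126, and fry, which asks whether the members move one way on balance and does not compare them with other genes, gave 0.0555. Without mutant replicate 1 or 2, 5 and 3 members fell, and without wild-type replicate 1 or 2, 5 and 11. These data are consistent with a joint fall but rest on 2 libraries per group.

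Other genes with low p outside the lists were the noncoding genes FIRRE, which fell by 0.87 on the log2 scale (SE 0.0822, edgeR adjusted p = 3.01e-08), and LINC01033, which rose by 0.80 (SE 0.0752, edgeR adjusted p = 3.01e-08), and the coding genes CRTAC1, CACNA2D2 and GNAS, which rose by 0.75, 0.63 and 0.35.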
